A study of Rattus norvegicus with 8 samples.

How the data were processed

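Liver RNA of adult male Sprague-Dawley rats, 78 to 86 days old, was measured on 8 Agilent two-colour arrays of 1 slide, 4 from control offspring and 4 from offspring of dams given mixed agonists of the aryl hydrocarbon receptor (AhR). Per the labels, the liver RNA carried Cy5 and a universal rat reference RNA from 14 cell lines carried Cy3 on every array, 200 ng of RNA were labelled, and no dyes were swapped. Each array held a pool of RNA from 2 rats, so that 8 pups stood behind each group. The labels do not say whether pups of different pools shared a litter, and p-values here measure the spread between pools. The study as a whole had 72 arrays and a second age of 21 days; those other arrays are not analysed here.

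The intensity values are the median pixel brightness of each spot and of its local background, which the authors deposited as written by Agilent Feature Extraction 10.7.3.1, per the file headers. The same deposited files hold processed signals that the scanner software had background-subtracted and dye-normalized, and a log10 ratio per spot, per the file headers. Mean spot intensities had been planned as input; median intensities were used in their place. The authors also deposited a value table in log2 units, whose scale is not stated. Set against the scanner values, its columns followed the log2 ratio of unsubtracted Cy5 over Cy3 medians after a loess fit, with a slope of 0.978 to 0.988 and r of 0.9898 to 0.9943 across probes. Its column medians lay between 0.00569 and 0.0165, its direction was Cy5 over Cy3, and the exact form of its dye correction stays unknown.

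Background was corrected by normexp with an offset of 50, and each array was normalized by loess in limma 3.58.1 under R 4.3.3, with control spots and outlier-flagged spots at weight 0. Spots of 1 probe were averaged without outlier-flagged spots. Of 62976 spots per array, 4259 were control spots, and the rest made up 30367 probes. Probes were kept where Cy5 was well above background on at least 4 of the 8 arrays, which left 17859. The share of probes with Cy5 well above background ran from 56.2% to 62.0% per array, and the number of arrays limits the precision. No probe was saturated in Cy5. Duplicate deposition was checked by setting arrays against each other: for probes with duplicate spots, the closest arrays differed by an SD of 0.17 (log2), against 0.06 expected from the spots alone.

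The files carry no gene names. RefSeq accessions of the probes were matched, without versions, to the RefSeq gene table of assembly GRCr8, which named 18004 probes, 11656 of them kept, for 10004 genes. Other probes were left unnamed, and no coordinates are given because the array was designed on an older build. A gene was represented by its kept probe with the highest mean Cy5 signal.

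Groups were compared with limma (lmFit and eBayes, Benjamini-Hochberg adjustment over all kept probes). For 39 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 was run on lists with at least 5 measured members, which were 38. The list of exocrine pancreas markers had 3 measured members and was not tested. Camera with an estimated correlation and fry were run beside it. Exact permutation tests were two-sided, and with 4 arrays per group their smallest p is 0.0286.

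Genes named in the text followed a rule fixed before the data were examined. Genes past an adjusted p of 0.05 came first, up to 12 in each direction, and where these were fewer than 20 the genes of smallest p filled the number to 20, as values only. Cyp1a1, Cyp1a2, Cyp1b1, Ahrr, Tiparp, Nqo1, Aldh3a1 and Ugt1a6 were named whatever their value, and so were the 3 members of smallest p in each of the 8 leading lists past the threshold. Tiparp had no matched probe. Genes named for the Cy3 channel or for their spread between arrays were chosen after their values were seen.

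The procedure was tested on simulated data for the comparison of AhR with control over 17859 probes. With 200 probes altered in independent noise, 51.2% were recovered at a fold of 1.5, 86.6% at 2 and 97.9% at 3, with 7.5 other probes called per run. With the alterations added to the normalized log2 ratios of the real arrays, the shares were 46.7%, 92.1% and 99.2%, with 0 other probes called. Folds of 1.5, 2 and 3 were mixed within each run. The alterations entered after background correction and normalization, so the shares hold for changes in the ratios and not for changes in RNA. In 20 runs of independent noise camera called 0 lists, and it called a list shifted by 0.3 (log2) in all 20. This noise held no correlation between genes, so these runs do not bear on false calls where genes of a list correlate. Alternatives covered the background correction, the normalization, the Cy5 channel alone, the filter on dim probes, blocks for replicate number and slide row, variance models, the value table and each array left out. Aquantile normalization between arrays leaves the log2 ratios unchanged, so that setting repeats the main fit and could not alter a result. A clock component as a covariate was added after seeing the data. All 8 arrays carried 1 scan date and lay on 1 slide, so that neither could be tested as a batch.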

Results

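Hepatic transcripts were profiled in adult male rats whose dams had received corn oil alone or a mixture of AhR agonists (non-ortho polychlorinated biphenyls, dioxins and furans) from gestation day 0 to postnatal day 20, at 1.8 ng per kg per day of dioxin toxic equivalents. Each group had 4 arrays, each of RNA pooled from 2 rats, taken at 78 to 86 days of age, well after exposure had ended. The AhR is a ligand-activated transcription factor that induces xenobiotic-metabolising enzymes. The comparison asks whether developmental exposure left a difference in liver gene expression in adulthood. The median Cy5 signal per array lay between 159 and 232 units over a background of 71 to 76.

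The channel labelled as reference carried abundant liver transcripts. Alb, which encodes serum albumin, had a mean log2 signal of 17.27 in Cy3 and 17.21 in Cy5, and Apoa1 had 16.72 and 16.37. The 20 hepatocyte markers had a median Cy5 minus Cy3 of 0.20 (log2). Fetal liver genes were brighter in Cy3: H19 by 46.5-fold, Afp, the fetal counterpart of albumin, by 17.7-fold and Igf2 by 16.4-fold. Cyp1a1 was at least 46.0-fold brighter in Cy3, with Cy5 well above background on 3 of the 8 arrays and taken at no less than the lowest such signal on the others. Skeletal muscle genes were also brighter in Cy3, with a median of -2.64 over 21 contractile genes, Tnnc2 at 14.9-fold and Myh8 at 12.4-fold among them. This median was -3.83 with Agilent processed signals and -2.58 with median centring. For some of these genes, Casq1 and Myh2 among them, Cy5 was not well above background on any array, so their folds are lower bounds. Male-biased rat liver genes were brighter in Cy5, with a median of 0.53 over 15 genes, Cyp2c11 at 0.95 and Obp3 at 0.83. These genes and the fetal and muscle lists were chosen after their values were seen, and without a dye swap the folds between channels are open to dye bias. Between arrays, processed Cy3 signals correlated across probes at 0.996 to 0.998, and Cy5 with Cy3 of the same array at no less than 0.988; probes are not independent replicates. As the same RNA stood in Cy3 on every array per the labels, the group comparison uses it only as a common denominator.

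**Figure D1:**
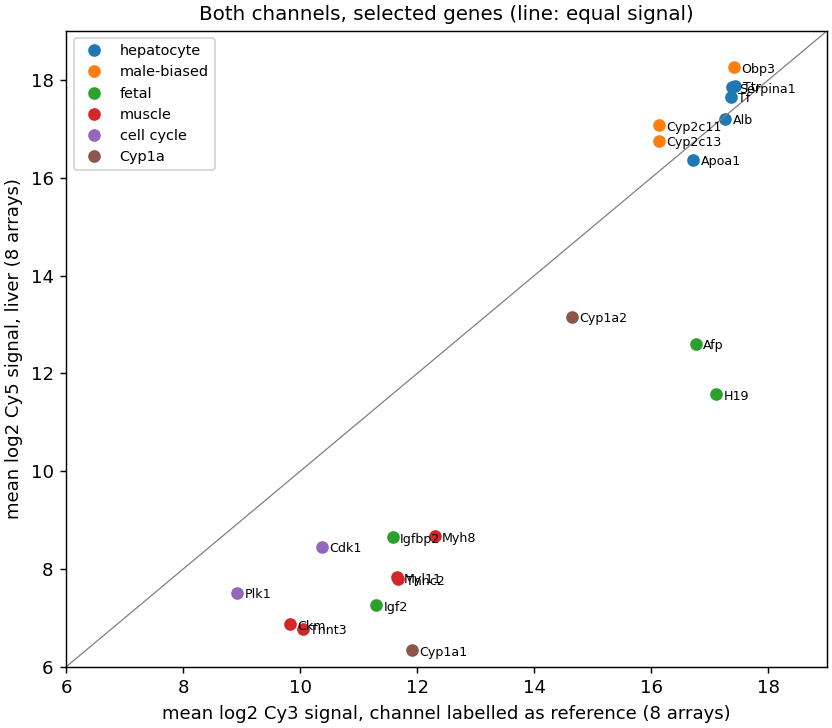
Mean log2 Cy5 signal (vertical) against mean log2 Cy3 signal (horizontal) over the 8 arrays for selected genes, each point a gene, after loess and Aquantile, with a line of equal signal. Alb lies near the line at 17.27 in Cy3 and 17.21 in Cy5, while H19 lies below it at 17.11 and 11.57.

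None of the classical AhR target genes passed the test between the groups. Cyp1a2, the constitutive hepatic member of the pair of marker enzymes, had a mean log2 ratio of -1.63 ± 0.43 (SD, n = 4) in control and -1.36 ± 0.45 (SD, n = 4) in AhR, a difference of 0.26 (SE 0.25, 95% interval -0.28 to 0.81, exact permutation p = 0.400). Cyp1a1, the most inducible AhR target, was well above background in Cy5 on 2 control arrays and 1 AhR array. Its log2 ratio was -5.43 ± 0.76 in control and -5.71 ± 0.72 in AhR (SD, n = 4 each), a difference of -0.28 (SE 0.43, exact permutation p = 0.629). With Cy5 not well above background on 5 of the 8 arrays, neither the size nor the direction of the Cyp1a1 difference can be read from these ratios, which gave 0.10 without control replicate 1. Nqo1, a quinone reductase, differed by -0.35 (SE 0.20) and Ugt1a6, a glucuronosyltransferase, by -0.25 (SE 0.23), and neither passed the test. Cyp1b1 and Ahrr, the AhR repressor, were not well above background in Cy5 on any array, and Aldh3a1 was on 1 AhR array. Aldh3a1, an aldehyde dehydrogenase, differed by 0.11, and by 0.76 with Agilent processed signals (limma unadjusted p = 0.00540, adjusted p = 1.00), at signals near background. The AhR-responsive list held 17 genes, of which 9 had a kept probe and were tested. Cyp1a1, Cyp1b1, Ahrr and Aldh3a1 were not among these, so the list test leaves these targets out. Of the 9 measured members, 2 had higher and 7 lower means in AhR, with a median difference of -0.10. Camera gave an adjusted p of 0.131, and adjusted p = 0.655 with an estimated correlation. None of the members passed over all genes tested, and 0 passed when adjusted over the list alone. Without control replicate 2 the list passed the threshold with a preset correlation (median -0.14, adjusted p = 0.0164) but not with an estimated one (adjusted p = 0.388), a setting added after the data were seen. The list median was -0.02 without control replicate 1 and -0.20 without AhR replicate 2 (adjusted p = 0.354 and 0.198), and -0.20 with Agilent processed signals and -0.16 with Cy5 alone (adjusted p = 0.103 and 0.0764).

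**Figure D2:**
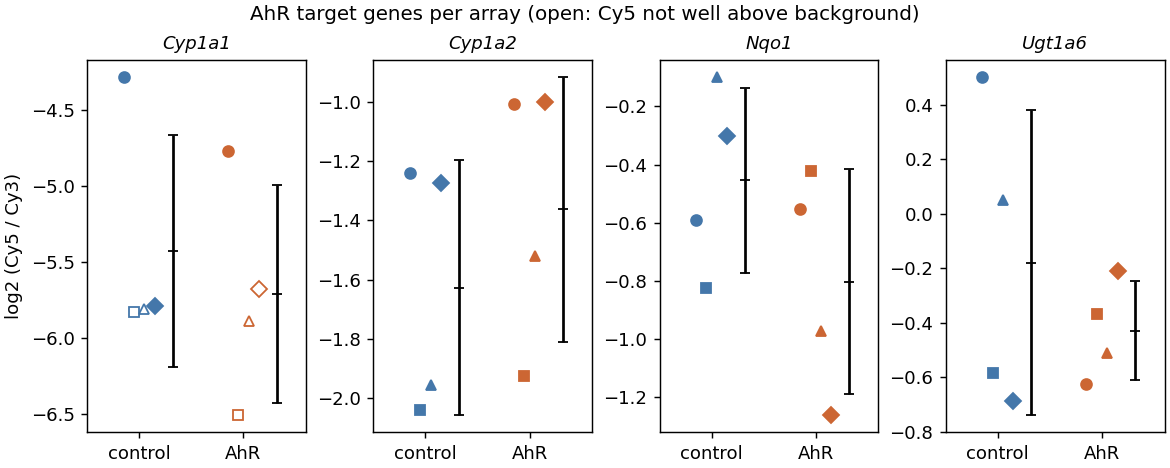
Log2 ratio of Cy5 to Cy3 per array for 4 AhR target genes, with marker shapes for replicates 1 to 4 and open markers where Cy5 was not well above background. Bars give the group mean and SD (n = 4), such as -1.63 ± 0.43 in control and -1.36 ± 0.45 in AhR for Cyp1a2.

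Across the transcriptome, the 20 genes of smallest p included aldo-keto reductases, hepcidin and a carnitine palmitoyltransferase, and none of them passed the test over all genes. Akr1c1, an aldo-keto reductase of steroid metabolism, differed by -0.82 (SE 0.17), and the related Akr1c13 by -1.03 (SE 0.32). Hamp, which encodes the iron-regulatory hormone hepcidin, differed by 0.68 (SE 0.17), from 0.22 ± 0.37 in control to 0.91 ± 0.15 in AhR (SD, n = 4 each). Hamp did pass when adjusted over the list alone, in the acute phase list (adjusted p = 0.0422, limma) and in the heme and iron list (adjusted p = 0.0362, limma). Both calls rest on the same probe, and no adjustment was made over the 38 lists. These calls held under 6 and 7 of 14 other settings, among them Aquantile between arrays, which leaves the ratios unchanged and repeats the main values. They were lost with Agilent processed signals, among others (limma adjusted p = 0.105 and 0.0897). They also ended without control replicate 2, control replicate 3 or any 1 of the AhR arrays (highest limma adjusted p = 0.162 and 0.139). Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, differed by 0.59 (SE 0.18), while Gpam, which starts glycerolipid synthesis, differed by -0.37 (SE 0.11) and the epoxide hydrolase gene Ephx2 by -0.39 (SE 0.12). Among genes of vessels and secreted factors, Esm1 differed by 0.61 (SE 0.15), Apln by 0.38 (SE 0.11), and Myh11, a smooth muscle myosin, by 0.45 (SE 0.14). The caspase genes Casp12 and Casp4 differed by 0.78 and 0.36, the lectin-like genes Clec2d2l1 and Clec2d2 by -0.80 and -0.35. The remaining genes of the 20 were Wsb1 at -0.50, Nrarp at 0.46, Aqp5 at 0.42, Mmp24 at 0.49, Cib2 at 0.81, Fam13a at -0.70 and Sorcs2 at 0.40. With Agilent processed signals 6 of the 20 differences were over 1.5 times as large, with adjusted p of 1.00: Esm1 at 1.04, Apln at 0.81, Myh11 at 0.97, Casp12 at 1.45, Clec2d2 at -0.80 and Sorcs2 at 0.63.

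Limma called 0 of 17859 probes at an adjusted p of 0.05, with a lowest adjusted p of 1.00. At an unadjusted p under 0.05 it gave 288 probes, 1.61% of those tested, against 893 by chance. Of these, 37 also differed by 1.5-fold or more, 17 higher and 20 lower in AhR. With median centring in place of loess this split was 26 to 14, and with Agilent processed signals 105 to 68. The groups did not overlap for 212 probes, 1.19% of them, against 2.86% by chance. The median SE of a difference was 0.12 (log2). In the ratios of the main processing, the 95% interval stayed within 2-fold in either direction for 17660 probes (98.9%). It stayed within 1.5-fold for 16401 (91.8%). These intervals depend on the processing and do not bound changes in RNA. The 37 probes became 173 with Agilent processed signals, and 30 to 46 under the other settings. How far the offset of the background correction narrowed the intervals of dim probes was not tested.

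Among the gene lists, genes of fatty acid oxidation and markers of stellate, endothelial and Kupffer cells were higher as lists in AhR, and genes of phase II metabolism, red cells, the cell cycle, endoplasmic reticulum stress and bile acids were lower, all by small amounts. These 9 of 38 lists passed camera's adjusted p of 0.05 with a preset correlation, and none did with an estimated correlation (adjusted p = 0.655 to 0.793) or with fry (lowest unadjusted p 0.151). The lowest exact permutation p of a list mean was 0.200 (n = 4 per group). Fatty acid oxidation genes, controlled by PPARA, had a median difference of 0.10, with 23 of 30 members higher, adjusted p = 0.00254, and adjusted p = 0.655 with an estimated correlation. Its leading members were Cpt1a, Cpt2 at 0.38 (SE 0.14) and Cyp4a2, a fatty acid hydroxylase, at 0.69 (SE 0.27). The call ended without AhR replicate 4 (median 0.06, adjusted p = 0.441), and the median was 0.06 without control replicate 2 and 0.15 without control replicate 4. Stellate cell and matrix genes had a median of 0.11, with 17 of 19 members higher, adjusted p = 0.00254, and adjusted p = 0.655 with an estimated correlation. Dcn, which encodes the matrix proteoglycan decorin, differed by 0.33 (SE 0.11), Col5a1 by 0.25 and Tgfb1 by 0.26. This call ended without control replicate 2 (median 0.06, adjusted p = 0.0755), and the median was 0.17 without control replicate 3 or control replicate 4 and 0.195 without AhR replicate 4. Endothelial markers had a median of 0.13, with 9 of 11 members higher, adjusted p = 0.0146, and adjusted p = 0.655 with an estimated correlation; Tie1 differed by 0.21, Oit3 by 0.36 and Lyve1 by 0.31. The endothelial median was 0.03 without AhR replicate 3 or control replicate 3 and 0.04 without control replicate 4, each of which ended the call (adjusted p = 0.132, 0.181 and 0.162), and 0.195 without control replicate 2. Kupffer cell and macrophage markers had a median of 0.12, with 15 of 18 members higher, adjusted p = 0.0489, and adjusted p = 0.793 with an estimated correlation. Their median turned to -0.06 without control replicate 1 and to -0.01 without AhR replicate 3 (adjusted p = 0.240 and 0.986). Without control replicate 4 the Kupffer call ended at a larger median of 0.18 (adjusted p = 0.162), and without control replicate 2 or 3 the median was 0.21 and 0.20. It also ended with Agilent processed signals (adjusted p = 0.0736) and with Cy5 alone (adjusted p = 0.0690), at medians of 0.13 and 0.12.

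Phase II genes, the transferases that conjugate xenobiotics, had a median of -0.12, with 16 of 24 members lower, adjusted p = 0.0108, and adjusted p = 0.655 with an estimated correlation. Gsta3 differed by -0.39 (SE 0.19), Sult1b1 by -0.40 (SE 0.20) and Mgst2 by -0.25 (SE 0.13). Without AhR replicate 1 the phase II median was -0.07 and the call ended (adjusted p = 0.0713), while without control replicate 4 it ended at a median of -0.12 (adjusted p = 0.224); without control replicate 1 the median was -0.07. Erythroid and blood markers had a median of -0.34, with 6 of 7 members lower, adjusted p = 0.0226, and adjusted p = 0.655 with an estimated correlation. Ahsp, a haemoglobin chaperone, differed by -0.70 (SE 0.43), Hbb by -0.56 (SE 0.38) and Slc4a1 by -0.32 (SE 0.24). The erythroid median was -0.10 without control replicate 2 and -0.17 without AhR replicate 3, which ended the call (adjusted p = 0.593 and 0.132). The call also ended without AhR replicate 4 and without control replicate 4 (adjusted p = 0.0839 and 0.162), where the medians were -0.30 and -0.45, and the median was -0.52 without AhR replicate 2. Cell cycle genes had a median of -0.17, with 15 of 20 members lower, adjusted p = 0.0226, and adjusted p = 0.748 with an estimated correlation; Bub1 differed by -0.27, Ccna2 by -0.35 and Ccnd1, a G1 cyclin, by 0.34. The cell cycle median was -0.05 without control replicate 3 (adjusted p = 0.496), and the call also ended without AhR replicate 1, AhR replicate 4 or control replicate 4 (adjusted p = 0.0907, 0.416 and 0.224), at medians of -0.13, -0.14 and -0.16. The median was -0.26 without control replicate 1 and -0.30 with Agilent processed signals, and the call ended with Cy5 alone (median -0.17, adjusted p = 0.0690). Endoplasmic reticulum stress and ATF4 targets had a median of -0.13, with 18 of 21 members lower, adjusted p = 0.0226, and adjusted p = 0.655 with an estimated correlation; the chaperone genes Dnajc3, Hyou1 and Sdf2l1 differed by -0.19, -0.24 and -0.24. For this list the median was -0.03 without control replicate 4 and -0.07 without AhR replicate 4 (adjusted p = 0.285 and 0.683), and the call also ended without AhR replicate 2 or control replicate 3 (adjusted p = 0.197 and 0.122), at a median of -0.10 for both. Genes of bile acid synthesis and transport had a median of -0.12, with 15 of 18 members lower, adjusted p = 0.0413, and adjusted p = 0.655 with an estimated correlation; the transporter genes Slco1b2 and Abcg5 differed by -0.32 and -0.59 and the reductase gene Akr1d1 by -0.34. The bile acid call ended without control replicate 1, control replicate 4, AhR replicate 2 or AhR replicate 3 (adjusted p = 0.354, 0.224, 0.197 and 0.220), at smaller medians of -0.07, -0.08, -0.09 and -0.09. Without control replicate 3 it ended at a larger median of -0.185 (adjusted p = 0.0560), which was also the median without control replicate 2, and with Agilent processed signals it ended at -0.10 (adjusted p = 0.0736). None of the members of these 9 lists passed over all genes tested, and 0 passed when adjusted over the list alone.

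Over all 38 lists, camera with an estimated correlation called 0 and fry called 0. Without control replicate 4, 3 lists passed, 2 of them among the 9, and without AhR replicate 4, 5 passed, all 5 among the 9. The other 29 lists had adjusted p of 0.0636 or more. Of these, 3 passed with a preset correlation under some of 8 other settings of normalization, signal or block: cholangiocyte markers under 3 (lowest adjusted p = 0.0133), fatty acid synthesis genes under 3 (0.0255; with median centring the test pointed down at a median of 0.01) and ribosomal protein genes under 2 (0.0214). With an estimated correlation, on all arrays, their adjusted p was 0.655, 0.767 and 0.788. With 1 array left out 13 of the 29 passed, among them interferon response genes without control replicate 1 (median -0.18 against -0.05, adjusted p = 5.31e-07; on all arrays adjusted p = 0.812 with an estimated correlation). CAR and PXR targets, which encode drug-metabolising enzymes, had a median of -0.05 and an adjusted p of 0.933, and NRF2 targets of the oxidative stress response a median of -0.05 and an adjusted p of 0.960; in both lists the test pointed upwards against the median. Thyroid hormone-responsive genes had a median of 0.01 (adjusted p = 0.603) and male-biased liver genes of 0.00 (adjusted p = 0.264). The hepatocyte markers, the main cell type of the tissue, had a median difference of 0.03, with 10 of 20 members higher and an adjusted p of 0.675.

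**Figure D3:**
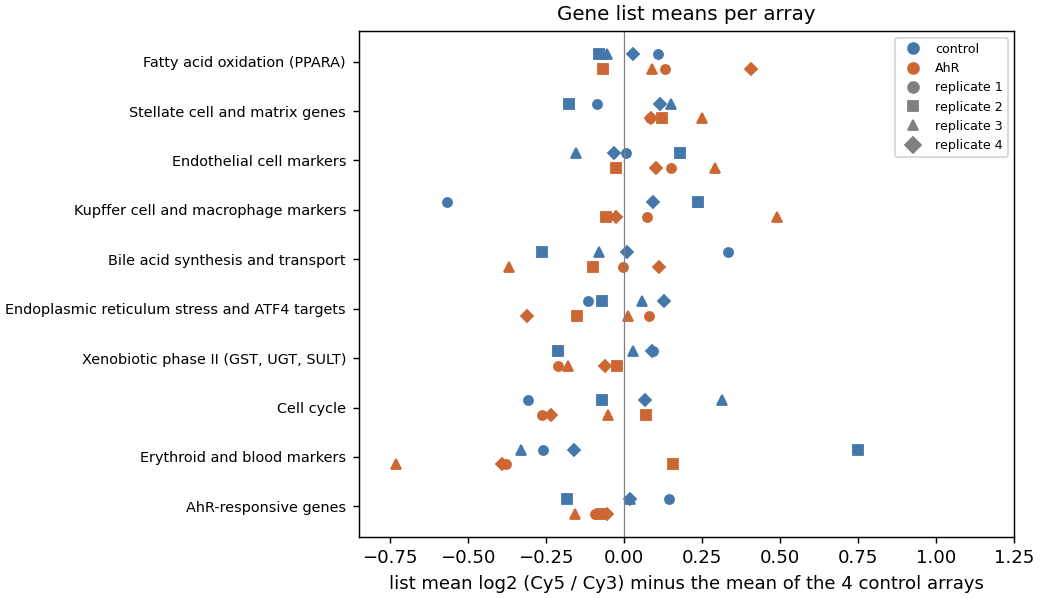
Mean log2 ratio of each list per array, minus the mean of the 4 control arrays, for the 9 lists past an adjusted p of 0.05 with a preset correlation and for the AhR-responsive list; marker shapes give replicates 1 to 4. The arrays of both groups overlap in each list shown, and control replicate 2 stands apart in the erythroid list.

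Arrays of the same group differed in genes of the circadian clock. Dbp, an output gene of the clock, had the largest SD within groups of all named genes measured, 1.32 (log2), against a median of 0.17 over 10004 genes, followed by Nr0b2, a repressor of bile acid synthesis, at 1.28. Dbp ranged from -2.21 on AhR replicate 4 to 1.41 on AhR replicate 1, and Bmal1, which encodes a core clock activator, ran against it, from 0.91 to -0.66 on the same arrays. Over the 8 arrays Dbp and Bmal1 correlated at r = -0.888 (exact permutation p = 0.00454) and rho = -0.881 (exact permutation p = 0.00724). Without the 2 arrays farthest from the median of Dbp r was -0.858, and within the slide rows of 4 arrays each it was -0.989 and -0.857. Of 35 pairs of a repressor-phase and an activator-phase clock gene, 29 correlated negatively and 7 passed after Benjamini-Hochberg adjustment of the exact permutation p (Dbp and Bmal1, adjusted p = 0.0258). These genes were chosen after their values were seen. The clock list as a whole had a median difference between groups of 0.10 (adjusted p = 0.121, camera, and adjusted p = 0.655 with an estimated correlation). Without AhR replicate 3 its median was 0.16 and it passed with a preset correlation (adjusted p = 0.0455). Its members were mixed in direction, 10 higher and 5 lower in AhR. Opposed differences of genes of opposite phase can cancel in these tests of direction, so they do not exclude a shift of phase between the groups. Fry for changes in either direction gave the list an unadjusted p of 0.446.

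**Figure D4:**
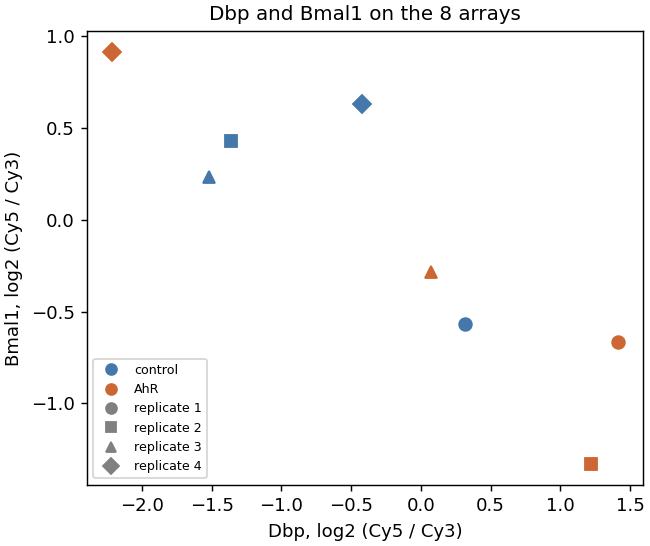
Log2 ratio of Cy5 to Cy3 of Bmal1 (vertical) against Dbp (horizontal), each point an array, with colours for the groups and shapes for replicates 1 to 4. The points run from high Bmal1 and low Dbp to low Bmal1 and high Dbp (r = -0.888, n = 8, exact permutation p = 0.00454).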

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

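The tests on the Cy3 channel in this part were chosen only after the result was seen. In the channel labelled as reference, 12 genes were at least 8-fold brighter in Cy3 than in Cy5 on all 8 arrays, a signal outside the comparison of groups, among them Cyp1a1, H19, Sult2a6, Akr1b7, A2m, Afp and Igf2. This count was 44 with Agilent processed signals and 10 with median centring. RNA of cell lines alone is argued against by the hepatocyte markers, whose median Cy5 minus Cy3 was 0.204 (0.0817 with Agilent processed signals and 0.521 with median centring). Cy5 light read in Cy3 is argued against as the main source by the slope of Cy3 on Cy5 deviations (log2) over the arrays, 0.0435 for the hepatocyte markers (-0.118 to 0.121 with 1 array left out) and 0.0453 for the 40 genes of largest Cy5 spread (0.0142 to 0.0521). Dye bias of single probes stays open for the fetal and muscle genes. The 5 of them with another probe above background had a median of -1.02 on that probe. This lay below the lowest of 10000 random probe lists matched on signal (-0.89). It was nearer to 0 than the median on their first probes (-2.23), by more than the bound set before the value was computed. Cy5 was not well above background on any array for 3 of these probes. For Igfbp2 and Tnnt1, with Cy5 above background on all 8 arrays, the other probe was at -3.15 and -0.545, against -2.93 and -0.58 on the first. The 6 muscle genes outside the 40 brightest in Cy3 over Cy5 had a median of -0.646, and 0.01% of random lists lay as low. A reference made from other tissues, liver of young or mixed animals among them, may account for the fetal, muscle and hepatocyte transcripts together, which stays an untested hypothesis.

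Of 176 tests for a single array standing apart within its group of 4, over the named genes and list means, 9 exceeded Dixon's 95% critical value, where chance gives about 1 in 20. Control replicate 1 stood apart in 4 of them. Its Cyp1a1 log2 ratio was -4.28 against -5.83 to -5.79 on the other control arrays, where Cy5 was not well above background on 2 of them. Its Sorcs2 value was -0.0648 against -0.573 to -0.534, its Cyp1b1 value, not above background, was -0.158 against -0.359 to -0.326, and its mean of retinoid genes was 0.278 against -0.132 to -0.0971. On control replicate 2 the erythroid and blood marker mean was 0.341 against -0.738 to -0.568. On AhR replicate 1, Nrarp was 0.159 against 0.316 to 0.342, Bub1 was -1.30 against -1.14 to -1.11, and the mean of oxidative phosphorylation genes was -0.269 against -0.0602 to -0.0483. On AhR replicate 3, Slc4a1 was -1.82 against -1.24 to -1.15.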

How the results depend on the processing

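The clock covariate, and the estimated correlation without control replicate 2, were chosen after seeing the data. The count of 0 probes past an adjusted p of 0.05 held under each alternative, with 172 to 818 probes at an unadjusted p under 0.05. The 37 probes past an unadjusted p of 0.05 and 1.5-fold became 173 with Agilent processed signals, 30 to 46 under the other settings, and 32 to 68 with 1 array left out (57 without control replicate 4, 68 without AhR replicate 4); the cause was not tested. The count of 9 gene lists became 2 with array weights, 0 with an estimated correlation and 0 with fry, and 3 to 13 with 1 array left out. The causes were not tested. For the estimated correlation, more than the correlation differs from the preset form. The AhR-responsive list, at an estimated correlation of -0.007 and so under the preset 0.01, still went from an unadjusted camera p of 0.0516 to 0.0895. The AhR-responsive list kept its direction, with a median of -0.200 to -0.0221 with 1 array left out and adjusted p of 0.0164 to 0.961 over all settings, and passed only without control replicate 2 with a preset correlation (-0.14). Cyp1a1 ran from -0.60 to 0.10 with 1 array left out and was 0.10 without control replicate 1, and has no value with probes above background on all 8 arrays; with 5 arrays not above background, its size and sign cannot be read. Cyp1a2 ran from 0.13 to 0.45. Of 50 named genes, 13 were over 1.5 times as large with processed signals, beyond those in the results Tgfb1 (0.43), Tie1 (0.44), Bub1 (-0.43), Ccna2 (-0.56), Cyp1a1 (-0.45) and Ahrr (-0.54). With Cy5 alone 5 were smaller by over 1.5 times, Ugt1a6 (-0.16), Bub1 (-0.18), Dnajc3 (-0.11), Hyou1 (-0.15) and Cyp1a1 (-0.14), and with the clock covariate Gsta3 was -0.58 and Cyp1a1 -0.44. With median centring the median of all probes was 0.0403, and list medians moved by over 1.5 times for 7 of the 9 lists with the calls held: fatty acid oxidation (0.155), stellate (0.188), endothelial (0.208), Kupffer (0.187), phase II (-0.0771), endoplasmic reticulum stress (-0.0524) and bile acids (-0.0379). Of the other named genes, Cyp1b1 turned to 0.20 with processed signals, 0.0051 with Cy5 alone and 0.0134 with array weights, and Ahrr to 0.0172 with Cy5 alone; with 1 array left out Cyp1b1 ran from -0.0585 to 0.0409 and Ahrr from -0.0411 to 0.0162. The causes were not tested. Neither was above background on any array, so signal over background limits both. No named gene passed under any setting, with a lowest adjusted p of 0.213. Over all kept probes, deviations of same-numbered arrays correlated at 0.00, -0.06, 0.05 and -0.37, which gives no sign of pairing by number. These values do not exclude shared deviations of single genes. Replicate numbers matched the slide columns on all 8 arrays, so a replicate block is also a block for slide column. With a replicate block the counts were 0 probes, 41 probes at 1.5-fold and 10 lists, and limma's unadjusted p went from 0.522 to 0.0923 for Cyp1a1 and from 0.306 to 0.0406 for Cyp1a2, with adjusted p of 1.00 for both; a balanced block leaves the differences of -0.28 and 0.26 as they are.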

Other observations

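The tests of the clock genes and of the clock covariate in this part were chosen only after the result was seen; the tests of other splits were not. Several liver genes varied widely between pools of the same group. After Dbp and Nr0b2, the genes of largest SD within groups were Ugt2b, Zfp354a, Onecut1, Noct, Bcl6 and Akr1c2, at 1.22, 1.17, 1.15, 1.14, 1.13 and 1.13 (log2). Dbp and Nr0b2 had higher means in AhR, with differences of 0.87 and 0.81, and Ugt2b and Akr1c2 had lower ones, with -1.86 and -1.29. Zfp354a, Onecut1, Noct and Bcl6 differed by -0.01, 0.24, -0.13 and -0.25. None of these differences passed the test. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had an SD of 0.96 and a difference of -0.01. Female-biased liver genes had a list SD within groups of 0.30 and a median difference of 0.05 (camera adjusted p = 0.603).

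The 9 lists past the threshold with a preset correlation do not exclude chance. Of the 35 splits of the 8 arrays into groups of 4, 17 gave as many lists, and the highest of the other splits gave 18. For the 37 probes past an unadjusted p of 0.05 and 1.5-fold, 26 of 35 splits gave as many, with a highest other of 213. For the 0 probes past an adjusted p of 0.05 the splits decide nothing, as any of the 35 gives at least 0; the highest other gave 2. Correlation between genes of a list across arrays may account for the list calls, which was not tested on its own. The calls went to 0 with an estimated correlation, but this cannot be credited to correlation alone. That form of camera also raised the unadjusted p where the estimate lay under the preset 0.01, from 0.0516 to 0.0895 for AhR-responsive genes and from 0.205 to 0.243 for p53 targets. An effect of exposure on these lists stays open.

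Fewer probes than chance gives had a low p, 1.61% of them at an unadjusted p under 0.05. The real grouping gave 288 such probes, the lowest of the 35 splits, while a split of control replicates 1, 2 and 3 with AhR replicate 4 against the rest gave 2848, which points to a structure of the samples across the groups. A clock covariate, the first principal component of the clock genes, brought the share to 2.05%, under the 3% set before this value was computed. This bears on the real grouping alone, and counts over the 35 splits varied widely, with a median of 672 against 893 by chance. The split with 2848 probes was not refitted with the covariate. The test therefore does not decide whether the differences between arrays held by that component are a source of the structure. Clock phase as a whole is not excluded either, since 1 linear component need not hold all differences in phase. Differences in feeding, litter or handling between pools were not tested and stay open.

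Clock genes of opposite phase moved against each other within groups. After removal of group means, 7 repressor-phase and 5 activator-phase genes correlated at a mean of -0.484 over the 8 arrays, below all of 10000 random gene lists matched on signal, whose middle 95% ran from -0.15 to 0.16. This is consistent with arrays that sampled different clock phases, as a hypothesis found and tested on the same data; times of tissue collection are not used here.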
